A study of Mus musculus with 2 samples.

How the data were processed

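Brown adipose tissue, the fat depot that burns lipid for heat, was taken from male C57BL6/J mice aged 8 to 12 weeks. All mice ate a diet with 60% of its energy as fat for 10 days, and the treated ones also received SML by intraperitoneal injection at 5 mg per kg body weight. The series title names sesaminol, a sesame lignan, while the labels give only the abbreviation SML, which is kept here. Poly(A) RNA was sequenced from TruSeq libraries per the labels' protocols. There was 1 library for the control diet (HFD control) and 1 for the treated mice (SML). How many animals or depots went into each library is not given in the sources used here.

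The deposited values came as 1 table of 14189 assembled transcripts with 10778 gene symbols, in which each library had a column of FPKM and a column headed count. FPKM (fragments per kilobase of transcript, scaled for library size) was computed by the authors, and per the submitters' processing notes the tools included CASAVA 1.8 and Cufflinks with the mouse build mm10. The aligner, the annotation release and any filter on transcripts are not given in the sources used here. The deposited count columns were not raw counts but a scaled signal of estimated counts: the low values of symbols with 1 transcript moved in steps of 0.637 in the HFD control column and 0.866 in the SML column. Taking these steps as the worth of 1 fragment, 91.3% of 527 low HFD control values and 91.2% of 763 low SML values of up to 20 steps were whole numbers of fragments within 0.1. Dividing by the step gave 12001476 fragments in the HFD control library and 8503628 in the SML library within the deposited table. The ratio of FPKM between the libraries was 1.002 times the ratio of scaled counts at the median transcript with over 20 scaled counts, so both columns carried the same scaling.

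The SML FPKM was listed at 0 in 1443 transcripts whose SML scaled count was above 0. The same held for the HFD control columns in 274 transcripts. For 939 of the 1443 the scaled count and the HFD control values implied an SML FPKM above 0.05. The highest HFD control FPKM among these 939 was 1.18. A deposited 0 in the SML column therefore did not mean that no fragment was counted, and 294 of the genes kept below had such a transcript. Spreadsheet software had turned 17 gene symbols into dates, and these rows carried no usable name. The table as used here held 0 mitochondrially encoded symbols. No sample column was left unused.

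Transcripts with the same symbol were summed to genes. The difference between the libraries was log2(FPKM + 1) in SML minus log2(FPKM + 1) in HFD control, which understates the change of genes with low values. Genes with a mean FPKM of at least 1 over both libraries were kept, which left 9887 genes. A gene was counted as higher or lower in the SML library when the difference reached 1.5-fold. With 1 library per group there was no test and no p-value. For single genes the ratio of scaled counts is given with a 95% exact conditional binomial interval on the fragments, which covers counting error only and neither the spread between animals nor duplicate molecules from PCR. Values were otherwise used with the scaling of the deposited table.

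Gene lists were fixed before the data were examined, as were the size rule, the filter, the pseudocount, the rule for named genes and the alternatives except those named as added. The 58 lists covered brown fat function, mitochondria, lipid and carbohydrate metabolism, signalling, stress, immunity and the markers of other cell types that a dissected depot can hold. For the 52 lists with at least 5 measured members the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list outside percentiles 2.5 to 97.5 is described as standing apart. By chance 2.6 of 52 lists would do so if the genes of a list varied independently, which genes of a shared function may not. The percentile is a description of these libraries and says nothing about other animals. Named genes were 18 genes chosen for the tissue, the 8 largest differences in each direction among genes with a mean FPKM of at least 5 (without predicted genes, clone names, small RNAs, receptor segments and pseudogenes), and up to 2 members at each end of a list. Genes named outside this rule are said to be chosen after their values were seen. Some members that the rule would name are not reported here.

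The procedure was tested on simulated fragments drawn with Poisson error around the mean of both libraries' scaled counts for the 9887 genes, at the depth given by each library's step. The size rule found 98% of 100 genes made 2-fold higher, 74% of 50 made 2-fold lower and 100% of 50 made 4-fold lower. From counting error alone 56 of 9687 unchanged genes passed the rule, and 0 of 7603 with at least 100 expected HFD control fragments did. The interval included a ratio of 1 for 95.5% of unchanged genes, and 5% of 200 random lists fell outside the percentile limits.

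The other settings tried were pseudocounts of 0.1 and 5, scaling by the median, by a trimmed mean (30% of differences and 5% of mean expression trimmed at each end) and by totals without the 50 highest genes, no filter, a mean FPKM of at least 5, the highest transcript per symbol, a 2-fold rule and random lists without matching. Settings added after seeing the data were SML FPKM rebuilt from scaled counts, a GC content and transcript length trend removed within 10 bins of each, a minimum of 30 fragments, and other lists without genes of the skeletal muscle list. A second list of 59 muscle genes, none of them in another list, was also added after seeing the data, for 1 test in the closing section. GC content and length came from the longest coding transcript of GENCODE M21 for 99.2% of the genes kept. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Coordinates are those of the deposited table on mm10, written 1-based, and span the transcripts of the symbol.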

Results

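The transcriptome of brown adipose tissue was measured by poly(A) RNA sequencing in mice fed a high-fat diet for 10 days without SML (HFD control) or with SML injected at 5 mg per kg body weight. Each group was represented by 1 library, with 12001476 fragments in the deposited table for HFD control and 8503628 for SML. There were no replicates, so every difference below has no replicate check, compares 2 libraries rather than 2 conditions, and carries an interval for counting error only. Abundance is given as FPKM, fold differences are ratios of scaled counts with their 95% intervals, and list medians are on the log2(FPKM + 1) scale as SML minus HFD control. Zic1, Srebf1, Mlxipl, Aldoa, Gapdh, Pkm, Slc2a4, Insr, Cd74, Cdh5 and Dbp fell outside the rule for named genes and were chosen after their values were seen. The 10 most abundant genes held 14.3% of the total FPKM in the HFD control library and 13.1% in the SML library.

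The comparison asked how brown fat gene expression under a high-fat diet differed with SML. Lpl, the lipoprotein lipase that releases fatty acids from circulating triglyceride, was 2.83-fold higher in the SML library (2.78 to 2.88; 335 against 951 FPKM). Fasn and Scd1, enzymes of fatty acid synthesis and desaturation, were 1.8-fold (1.78 to 1.82) and 1.74-fold (1.72 to 1.75) lower. Ucp1, the uncoupling protein that makes brown fat thermogenic, stood at 8702 FPKM in HFD control and 7955 in SML, a ratio of 0.912 (0.905 to 0.919). In the SML library 11 of 15 antigen presentation genes were lower and 0 higher. Of 19 macrophage markers 8 were lower and 1 higher, and of 16 clock genes 6 were higher and 1 lower. Transcripts of skeletal muscle fibres were lower, such as Acta1 (16.8-fold, 15.6 to 18.2).

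By the 1.5-fold rule 538 of 9887 genes were higher and 569 were lower in the SML library, and 8780 (88.8%) were neither. The interval of the count ratio excluded 1 for 522 of the higher and 539 of the lower genes. A 2-fold difference was reached by 66 higher and 194 lower genes, and 31 of the 569 lower genes belonged to the skeletal muscle list. The second list of muscle genes, added after seeing the data, held 34 further lower genes among 40 measured. Muscle genes outside both lists, such as Ckmt2, were lower too, so these counts do not give the full share of muscle genes. The middle of the distribution was narrow, with quartiles of -0.21 and 0.22 around a median of 0. Across genes the difference was related to GC content (Spearman rho -0.33) and transcript length (0.16), where genes are not independent replicates, and 351 genes were higher and 509 lower once this trend was removed. With totals equal outside the 50 highest genes the balance turned, to 657 higher and 490 lower. Of the genes named below as higher or lower, Dio2, Ebf1, Gabpa, Elovl6, Insr, Fnip1, Cpa3, Rpl5, Psmc6 and Chordc1 were no longer higher, and Aldoa, Gapdh, Pkm, Cdh5, Gpihbp1, Hilpda, Dhcr7, Tgfbi, Nr1d1, Psmb5 and Cdkn1a no longer lower, by the size rule with the GC and length trend removed. Among the 52 testable lists 6 stood apart as higher, 21 as lower and 25 lay within the random range.

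**Figure D1:**
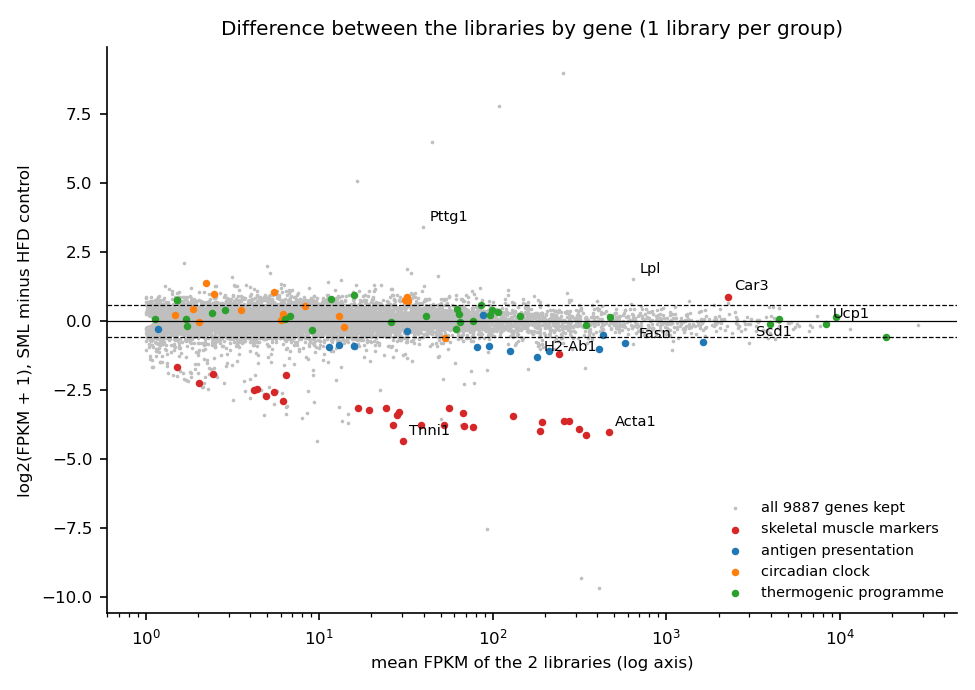
Each point is a gene kept, with mean FPKM of the 2 libraries on a log axis against the SML minus HFD control difference of log2(FPKM + 1), 1 library per group, and dashed lines at 1.5-fold. Skeletal muscle genes (red) lie far below 0 except Car3, antigen presentation genes (blue) mostly lie below the lower line, clock genes (orange) mostly lie above 0, and the grey points beyond 5 on either side are small RNA genes with at most 3 fragments in a library.

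Genes of the thermogenic programme were slightly higher in the SML library as a group. Of 31 measured members 4 were higher, 0 were lower and 27 were neither, with a median of 0.15 at percentile 99.3, beside the skeletal muscle list at a median of -3.32. Acot2, a mitochondrial acyl-CoA thioesterase, was 1.98-fold higher (1.70 to 2.32), and Dio2, which makes active thyroid hormone within the tissue, was 1.79-fold higher (1.62 to 2.0; 8.34 against 15.0 FPKM). Zic1, a transcription factor of classical brown fat, stood at 0.86 and 2.17 FPKM, and Fgf21, a secreted metabolic regulator, at 0.89 and 2.15 FPKM with a ratio of 2.41 whose interval (1.01 to 6.20) rested on 9 and 16 fragments. Ppargc1a, a coactivator of mitochondrial biogenesis, had a ratio of 1.44 (1.18 to 1.76), under the size rule. Of the abundant members besides Ucp1, Cpt1b had a difference of 0.15, near the list median, while Cidea had a ratio of 1.04 (1.02 to 1.05), Elovl3 of 0.982 (0.913 to 1.06) and Cox8b, a subunit of cytochrome c oxidase, of 0.659 (0.649 to 0.669) with 22044 and 14824 FPKM. Prdm16, a determinant of brown fat identity, was 3.44-fold lower (2.36 to 5.20) but had 155 and 33 fragments and a mean FPKM of 0.915, below the filter. With the GC and length trend removed the Dio2 difference was 0.55, just under the size rule, and that of Ppargc1a was 0.08.

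The beta-adrenergic and cAMP list, the route by which sympathetic nerves activate brown fat, had a median of 0.27 at percentile 99.9, with 5 of 18 members higher and 2 lower, or 3 higher with the GC and length trend removed. Crem, a transcription factor gene of this pathway, was 2.20-fold higher (1.59 to 3.09), whereas Rgs2 was 2.65-fold lower (2.39 to 2.93) and Nr4a1 2.01-fold lower (1.79 to 2.27). Adrb3, the main beta-adrenergic receptor of fat cells, had a ratio of 0.810 (0.758 to 0.866). The creatine and calcium cycling list was lower, with 6 of 10 members lower, 0 higher, a median of -0.84 and percentile 0. Its lowest members were Atp2a1 and Ckmt2, a calcium pump and a creatine kinase of muscle, while Ckb (56.4 against 57.3 FPKM) and Alpl (10.1 against 11 FPKM) were similar. The skeletal muscle list had a median of -3.32 in the same libraries. Leaving out its genes removed only Atp2a1 from the measured members of the creatine and calcium list. The other 9 measured members, of which 5 were lower with a median of -0.82, still included muscle transcripts such as Ckmt2. Beige and white adipocyte genes had a median of -0.26 at percentile 1.32, with 1 of 13 members higher and 5 lower, among them Serpina3c (2.18-fold lower, 1.55 to 3.10) and Retn, which encodes resistin (1.84-fold lower, 1.66 to 2.05). Without a filter on low genes this list lay at percentile 2.76, within the random range. The adipokine genes Adipoq and Lep had ratios of 0.782 (0.767 to 0.798) and 0.837 (0.748 to 0.937). Adipogenesis regulators lay within the random range (median 0.03, percentile 75.1), with 3 of 19 members higher, including Ebf1 (1.90-fold, 1.60 to 2.25) and Cebpb (1.69-fold, 1.60 to 1.78), 0 lower and a Pparg ratio of 1.07 (1.01 to 1.12).

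The lists of nuclear genes of the respiratory chain differed little. None of the 37 complex I subunits passed the size rule (0 higher, 0 lower), with a median of -0.15 at percentile 5.80, and their differences ran from -0.44 for Ndufa12 to 0.38 for Ndufs4. That median lay at percentile 0.88 among random lists not matched on expression. Of 39 genes of complexes II to V 0 were higher and 1 was lower, Atp5g1 (4.55-fold, 3.73 to 5.60), and the list median was -0.10 at percentile 25.2. Cox6a2, a cytochrome c oxidase gene known from striated muscle and outside this list, was 15.6-fold lower (11.2 to 22.4). The tricarboxylic acid cycle (0 of 22 past the rule, median -0.09, percentile 36.4) and mitochondrial ribosomal proteins (1 of 49 higher, 0 lower, median -0.01, percentile 65.7) also lay within the random range. Fatty acid oxidation had a median of 0.05 at percentile 94.1, with Acot2 as the 1 of 24 members that was higher and 0 lower, and Cpt1b, the carnitine transferase that admits fatty acids to mitochondria, had a ratio of 1.11 (1.08 to 1.13). Among genes with a mean FPKM of at least 5 that list stood at percentile 97.9, above the upper limit. The mitochondrial biogenesis, dynamics and quality control list lay at the upper limit (median 0.13, percentile 97.52), with 1 of 27 members higher, Gabpa (1.83-fold, 1.57 to 2.13), and 0 lower. Its percentile was 71.7 with the GC and length trend removed, and 3 other settings also placed it within the random range (95.3 to 97.47). Peroxisomal genes had 0 of 21 members past the rule, a median of 0.06 and percentile 86.4. The skeletal muscle list, whose fibres are rich in mitochondria, was lower at a median of -3.32 beside these lists.

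Genes of de novo lipogenesis were lower in the SML library. Of 22 members 1 was higher and 4 were lower, and the median of -0.26 lay at percentile 0.07. Acly, which supplies cytosolic acetyl-CoA, was 1.89-fold lower (1.83 to 1.96) and joined Fasn and Scd1 (3816 against 2200 FPKM). Fads2, a desaturase at 1.93 and 0.46 FPKM, was the lowest member at 4.17-fold (1.73 to 12.2). Elovl6, a fatty acid elongase, went the other way and was 1.76-fold higher (1.67 to 1.86), though 0 of 22 members were higher with the GC and length trend removed. The transcription factor genes Srebf1 and Mlxipl, which drive the pathway, had ratios of 1.17 (1.12 to 1.22) and 1.15 (1.06 to 1.25). Genes of the skeletal muscle list were also lower in this library at a median of -3.32, and none of them is in the lipogenesis list.

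Other lipid lists lay within the random range. In fatty acid and lipoprotein uptake (median 0.04, percentile 79.4) 1 of 18 members was higher, Lpl, and 3 were lower. With the GC and length trend removed 3 were higher and 1 was lower. Angptl4 and Gpihbp1, whose products inhibit the lipase and anchor it to capillaries, were 1.76-fold (1.68 to 1.86) and 1.68-fold (1.56 to 1.81) lower, and Cd36, a fatty acid transporter, had a ratio of 1.05 (1.03 to 1.08) whose log2 difference turned to -0.16 with the GC and length trend removed. Triglyceride synthesis had 0 of 14 members past the rule, a median of 0.06 and percentile 85.2. Lipolysis and lipid droplet genes had a median of 0.03 at percentile 82.4, with 0 of 18 higher and 2 lower, Fitm1 (23.3-fold, 9.76 to 72.6) and Hilpda (1.66-fold, 1.26 to 2.21), and a ratio of 1.04 (1.03 to 1.05) for Pnpla2, the triglyceride lipase. Cholesterol synthesis had a median of -0.09 at percentile 12.5, with 0 of 22 higher and 2 lower, including Dhcr7 (1.65-fold, 1.38 to 1.98), and 0 past the rule with the GC and length trend removed.

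Glycolytic genes were lower in the SML library, with 0 of 22 members of the glucose uptake and glycolysis list higher, 6 lower, a median of -0.40 and percentile 0. With the GC and length trend removed 3 were lower. The lowest were Eno3, an enolase of muscle (9.68-fold, 8.12 to 11.6), and Hk1, a hexokinase (2.51-fold, 2.17 to 2.92). Aldoa (5223 against 3266 FPKM), Gapdh (4723 against 3030 FPKM) and Pkm (1424 against 914 FPKM) were lower as well, while Slc2a4, the insulin-responsive glucose transporter, had a ratio of 0.875 (0.841 to 0.909). Skeletal muscle genes were lower at a median of -3.32, and leaving out genes of that list removed only Eno3. Of the other 21 members, which still included Aldoa, the aldolase of muscle, 5 were lower with a median of -0.34 at percentile 0.02. Glycogen metabolism lay within the random range (median -0.09, percentile 17.3), with 0 of 17 higher and 2 lower, Pygm (13.1-fold, 10.8 to 16.2) and Phka1 (3.17-fold, 2.15 to 4.70), both muscle forms. Insulin signalling genes stood apart as higher, at a median of 0.23 and percentile 99.3, with 3 of 18 higher and 0 lower. With the GC and length trend removed 1 of 18 was higher and the percentile was 99.6. Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, was 2.12-fold higher (1.89 to 2.39) and Insr, the insulin receptor, 1.72-fold (1.5 to 1.98). AMPK and sirtuin genes had a median of 0 at percentile 50.5, with 1 of 18 higher, Fnip1 (2.24-fold, 1.74 to 2.89), and 1 lower, Prkag2 (1.66-fold, 1.5 to 1.84), while 0 were higher with the GC and length trend removed.

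Antigen presentation genes were lower in the SML library. Of 15 members 0 were higher and 11 were lower, with a median of -0.90 at percentile 0. H2-Ab1 and H2-Aa, class II genes that display peptides to helper T cells, were 2.51-fold (2.34 to 2.70) and 2.14-fold (2.0 to 2.28) lower, and Cd74 went from 550 FPKM in HFD control to 271 in SML. All 6 class II members were lower (median -1.05), as were 5 of 9 class I and immunoproteasome members (median -0.75), with Tapbp as an exception at a ratio of 1.17 (1.11 to 1.24). The interferon response had a median of -0.39 at percentile 0, with 0 of 24 members higher and 7 lower. Igtp and Iigp1, interferon-induced GTPases, were 3.54-fold (3.27 to 3.84) and 2.46-fold (2.21 to 2.73) lower, yet Gbp3 (1.52-fold, 1.30 to 1.79) and Cxcl10 (1.52-fold, 1.05 to 2.21) had ratios above 1. Macrophage markers moved with these genes, at a median of -0.49 and percentile 0, with 8 of 19 lower and 1 higher. Lyz1 was 2.63-fold lower (2.11 to 3.30) and the complement gene C1qc 1.93-fold lower (1.67 to 2.22), whereas Cd14 was 1.77-fold higher (1.35 to 2.33). Erythroid markers were lower beside them, with 0 of 8 higher, 6 lower, a median of -0.88 and percentile 0, led by the globin genes Hba-a2 (3.31-fold, 3.02 to 3.62) and Hbb-bs (2.53-fold, 2.06 to 3.12). With the GC and length trend removed the median of the 6 erythroid members with a GC content and length value was -0.58, with 3 lower.

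Inflammatory cytokines and chemokines had a median of -0.20 at percentile 0.81, with 1 of 21 higher, Il18 (3.26-fold, 1.07 to 11.8), and 5 lower, led by Ccl8 (2.65-fold, 1.91 to 3.74). That list lay within the random range with the GC and length trend removed (percentile 6.68), at a mean FPKM of at least 5 (8.55) and with the highest transcript per symbol (3.43). Acute phase genes had a median of -0.31 at percentile 0.81, with 0 of 10 higher and 3 lower, including Hpx (5.74-fold, 2.26 to 18.7), but percentile 14.4 without a filter on low genes and 2.88 with at least 30 fragments. Hepatocyte markers, which share Fgb with the acute phase list, were lower with a median of -1.48, and macrophage and erythroid markers were lower beside both lists. T and NK cell markers lay within the random range (0 of 10 past the rule, median -0.12, percentile 14.8), as did mast cell and eosinophil markers (2 of 6 higher, 0 lower, median 0.15, percentile 79.7), where Cpa3 was 2.22-fold (1.21 to 4.15) and Tpsb2 1.83-fold (1.03 to 3.29) higher. Lists with too few measured genes gave single values only. Among B and plasma cell markers Jchain was 4.84-fold lower (2.74 to 9.19) and Cd79b stood at 2.15 and 1.42 FPKM. The neutrophil markers S100a8 and S100a9 stood at 1.07 and 4.17 FPKM in HFD control and 3.93 and 3.62 FPKM in SML, with 3 and 8 fragments for S100a8, and Ly6c2 at 6.92 and 4.48 FPKM.

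Genes of skeletal muscle fibres showed the largest differences of any list. Of 32 measured members 31 were lower and 1 was higher, with a median of -3.32 at percentile 0, and the median ratio of counts was 13.2-fold. Tnni1 and Tnni2, the slow-fibre and fast-fibre troponin I genes, were 31.2-fold (19.0 to 52.9) and 18.1-fold (15.5 to 21.2) lower, and the most abundant member besides Car3 in HFD control, Acta1, stood at 881 and 52.5 FPKM. Myl1 differed less, at 2.26-fold (2.11 to 2.44). The exception was Car3, a carbonic anhydrase that fat cells also express at high levels, which was 1.83-fold higher (1.8 to 1.86; 1598 against 2936 FPKM). Transcripts made by liver cells were lower too, at low levels: of 9 measured hepatocyte markers 0 were higher and 7 were lower, with a median of -1.48 at percentile 0. Alb, the serum albumin gene, stood at 6.40 FPKM and 158 fragments in HFD control and at 0 fragments in SML, and Apoa1, an apolipoprotein gene, was 30.6-fold lower (8.19 to 256) with 83 and 2 fragments. Mural and smooth muscle markers had a median of -0.34 at percentile 0.05 with 0 of 15 higher and 5 lower, and their upper quartile was -0.05. The lowest were Tpm2 (6.53-fold, 5.95 to 7.19), a tropomyosin shared with skeletal muscle, and Rgs5, a pericyte gene (2.03-fold, 1.62 to 2.54). The highest members, Myh11 and Cnn1, which mark smooth muscle, had ratios of 1.35 (1.13 to 1.62) and 1.23 (0.771 to 1.95).

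Endothelial markers had a median of -0.33 at percentile 0, with 0 of 20 higher and 4 lower (2 lower with the GC and length trend removed), led by the tight junction gene Cldn5 (2.87-fold, 2.47 to 3.35) and Gpihbp1. The 4 lower members also included Cdh5 (1.67-fold, 1.54 to 1.82). Angiogenesis genes lay within the random range (1 of 16 higher, 0 lower, median -0.15, percentile 5.70), with Nrp1 1.65-fold higher (1.55 to 1.76), and stood at percentile 1.97 with the GC and length trend removed. Fibroblast and preadipocyte markers had a median of -0.17 at percentile 2.45, with 2 of 18 higher (Pi16 and F3) and 2 lower (Ly6a and Ly6c1). That list lay within the random range with a pseudocount of 5 (percentile 7.04), without a filter (2.71) and with the highest transcript per symbol (2.60). Collagens and extracellular matrix genes had a median of -0.18 at percentile 0.22, with 1 of 32 higher, Col12a1 (2.13-fold, 1.77 to 2.58), and 2 lower, Timp1 (3.04-fold, 1.28 to 9.47) and Tgfbi (1.64-fold, 1.30 to 2.08), and percentile 2.88 after trend removal. Schwann and nerve markers had a median of -0.37 at percentile 0.88, with 0 of 6 higher and 2 lower, but percentile 4.67 without a filter on low genes and 2.89 with the highest transcript per symbol. Single values were available for Flt4 (lymphatic endothelium, 1.19 and 0.82 FPKM), Igfbp6 (mesothelium, 20.3 and 18.1 FPKM) and the epithelial genes Sfn (2.01-fold higher, 1.15 to 3.57) and Krt10 (1.85 and 2.15 FPKM).

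**Figure D2:**
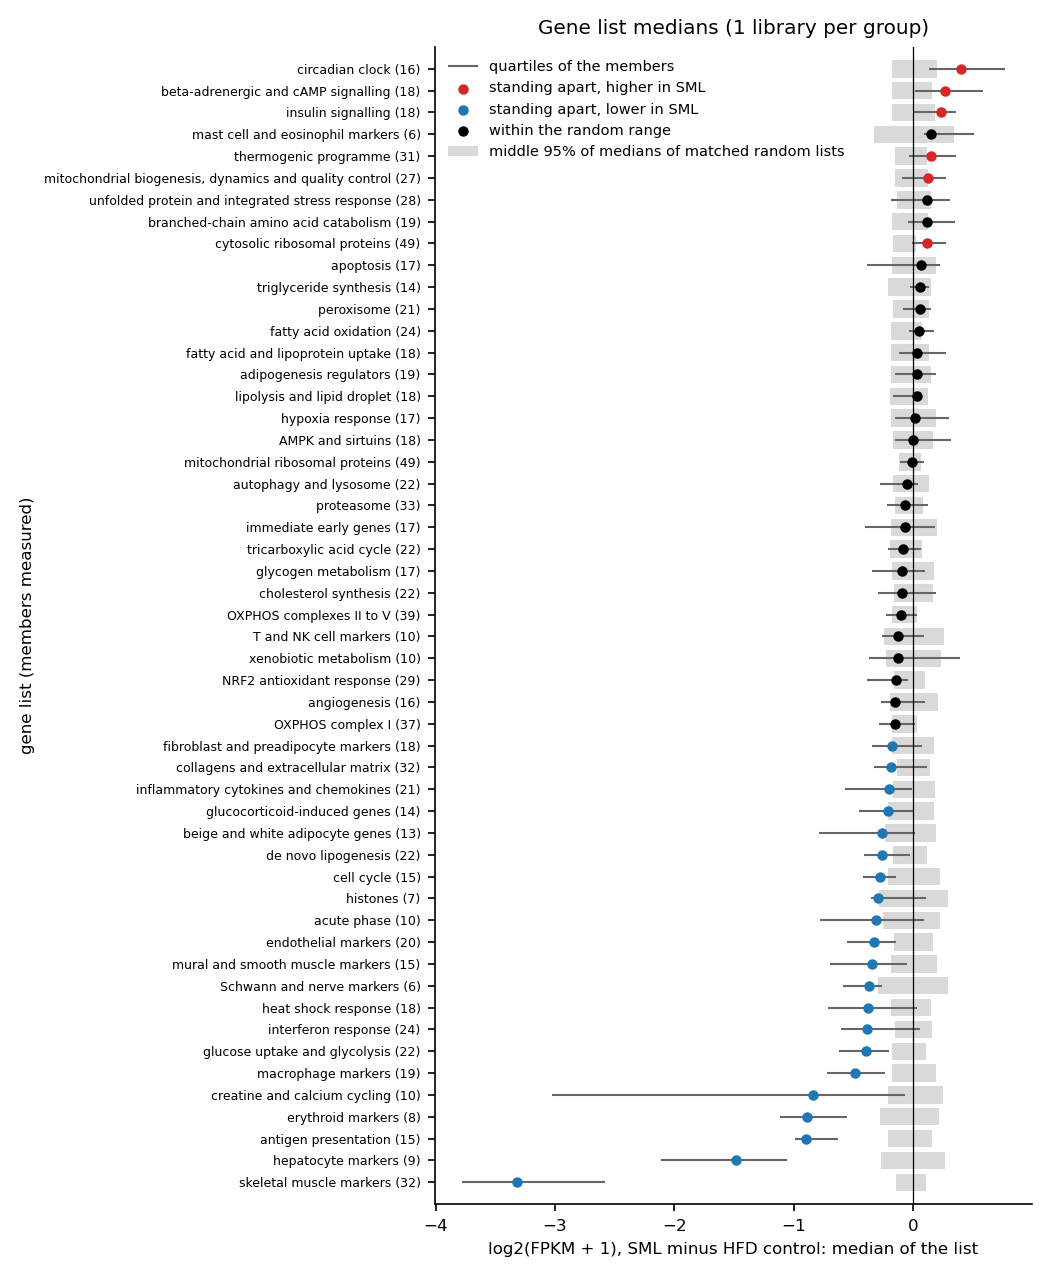
Median SML minus HFD control difference of log2(FPKM + 1) for the 52 lists with at least 5 measured members (points, members measured in brackets), with quartiles of the members as lines and the middle 95% of medians of matched random lists as grey bars. The circadian clock list has the highest median (0.41) and the skeletal muscle list the lowest (-3.32), and 27 of the medians lie outside their grey bars.

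Clock genes had the highest median of all lists. Of 16 measured members 6 were higher, 1 was lower and 9 were neither, with a median of 0.41 at percentile 99.99. Ciart (4.50-fold, 2.37 to 9.11) and Nr1d2 (2.36-fold, 1.97 to 2.84), both repressors in the clock loop, were the highest members by the log2 difference, and Dbp, a clock output gene, was 1.85-fold higher (1.63 to 2.10). Nr1d1, the paralogue of Nr1d2, was 1.55-fold lower (1.44 to 1.67). The time of day at collection was not among the sample details used here. Cytosolic ribosomal proteins were slightly higher as a group, with 3 of 49 higher, 0 lower, a median of 0.12 (0.24 with the GC and length trend removed) and percentile 99.99, led by Rpl14 (1.65-fold, 1.57 to 1.73) and Rpl5 (1.61-fold, 1.54 to 1.69), while Rps14 was 1.41-fold lower (1.37 to 1.46), within the size rule. Proteasome genes lay within the random range (1 of 33 higher, 1 lower, median -0.07, percentile 27.8), with Psmc6 1.51-fold higher (1.35 to 1.69) and Psmb5 1.57-fold lower (1.49 to 1.66).

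Heat shock genes were lower in the SML library, with 7 of 18 lower, 1 higher, a median of -0.37 and percentile 0.01. Cryab, a small heat shock protein abundant in muscle, was 4.88-fold lower (4.19 to 5.73), and Hspa1a, the inducible Hsp70, 5.76-fold lower (3.46 to 10.2) at 3.83 and 0.67 FPKM. Chordc1 was 1.68-fold higher (1.33 to 2.12). Skeletal muscle genes were lower beside these, at the median of -3.32. Glucocorticoid-induced genes had a median of -0.21 at percentile 2.21, with 0 of 14 higher and 2 lower, Angptl4 and Cdkn1a, but percentile 4.26 after trend removal, 5.79 with a pseudocount of 5 and 3.38 without a filter. Cell cycle genes had a median of -0.28 at percentile 0.52 with 0 of 15 past the rule in either direction, but percentile 3.04 after trend removal and 2.54 without a filter. Histones had a median of -0.29 at percentile 2.41 with 0 of 7 past the rule. They lay within the random range under 9 other settings, at percentile 73.8 with a mean FPKM of at least 5 and 74.2 with at least 30 fragments, where 5 members were left, and at 2.52 to 7.20 under the others.

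The largest differences were taken from genes with a mean FPKM of at least 5, leaving out small RNAs, predicted and clone-named genes, receptor segments and pseudogenes. On the positive side Pttg1, which encodes securin, an inhibitor of sister chromatid separation (chromosome 11, 43420248 to 43426248), was 12.0-fold higher (8.79 to 16.7), with 45 fragments in HFD control and 397 in SML. Tmed5, a gene of vesicle transport (chromosome 5, 108121647 to 108132591), was 3.43-fold higher (3.14 to 3.74) and Cish, a cytokine-induced inhibitor of STAT5 signalling (chromosome 9, 107296689 to 107301961), was 3.12-fold higher (2.84 to 3.44). Pdzd9 (4.62-fold, 3.15 to 6.94), Gt(ROSA)26Sor (3.25-fold, 2.45 to 4.34), Dhdh (2.61-fold, 2.31 to 2.96) and Slc4a4 (2.60-fold, 2.39 to 2.82) completed the 8 largest with Lpl (chromosome 8, 68880555 to 68906932). Within the same selection the 8 largest negative differences all belonged to genes known from striated muscle: Tnni1, Tnni2, Acta1 (chromosome 8, 123891758 to 123894775), Ckm (16.9-fold, 14.9 to 19.3), Mylpf (15.6-fold, 13.6 to 18), Myl2 (15.9-fold, 11.6 to 22.5), Atp2a1 (15.8-fold, 14.0 to 18) and Cox6a2 (15.6-fold, 11.2 to 22.4). On the same build Ucp1 lay on chromosome 8 from 83290348 to 83298456, Fasn on chromosome 11 from 120805958 to 120824547, Scd1 on chromosome 19 from 44394450 to 44407709 and H2-Ab1 on chromosome 17 from 34263227 to 34269418.

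**Figure D3:**
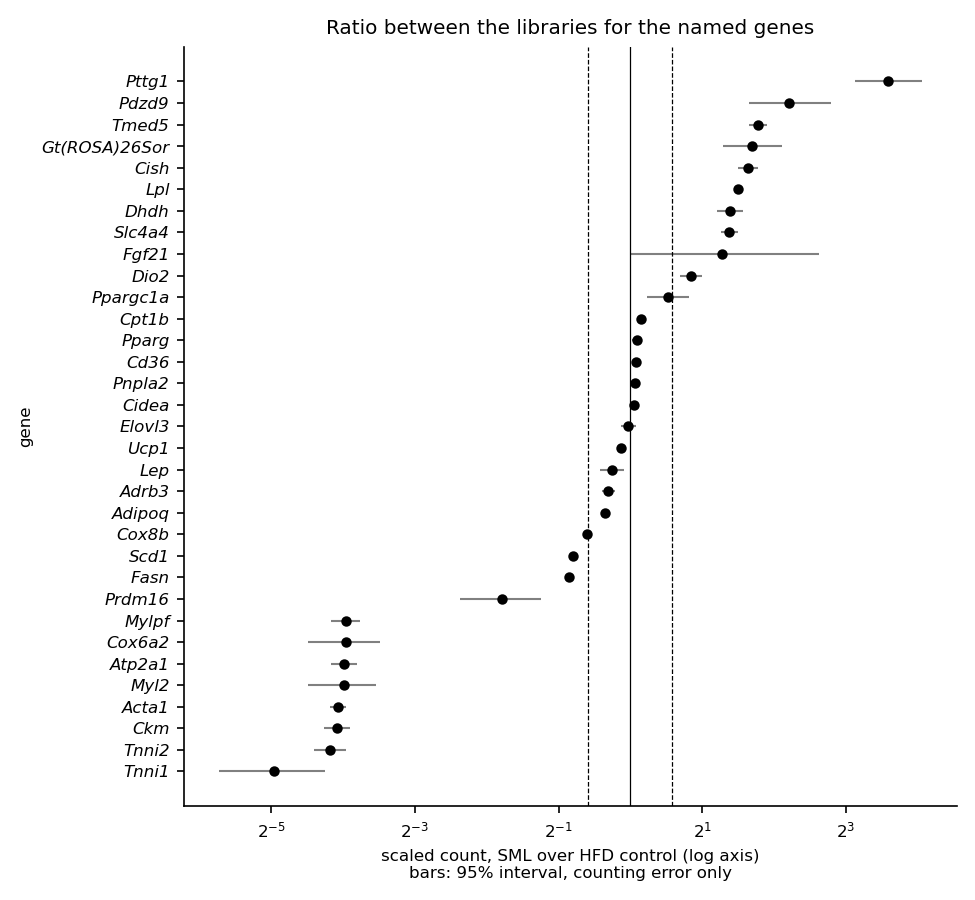
Ratio of scaled counts, SML over HFD control, on a log axis for the 18 genes chosen for the tissue and the 8 largest differences in each direction, 1 library per group, with bars for the 95% interval from counting error only and dashed lines at 1.5-fold. Pttg1 lies highest at 12.0, Ucp1 lies at 0.912, and the muscle genes form a separate cluster at the lower end.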

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

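Removal of the GC content and length trend, the rebuilt SML FPKM, the minimum of 30 fragments and the lists without skeletal muscle genes were chosen after the result was seen. Both counts and the list calls were recomputed under these, as far as each applied, and under 9 other settings each. Of the 27 lists standing apart, 17 did so under every alternative run and 10 lost it under at least 1, while 6 others gained it under at least 1. No list call changed direction under any of these. The 3 scalings moved the median of all genes by at most 0.047.

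Counts of genes depended on how low values were treated: 847 were higher and 833 lower with a pseudocount of 0.1, and 165 higher and 254 lower with a pseudocount of 5. A mean FPKM of at least 5 left 6156 genes with 319 higher and 306 lower, and the 2-fold rule left 66 and 194. Without a filter 571 of 10723 genes were higher and 1117 lower. These counts and the list percentiles without a filter took in more genes whose SML FPKM was listed at 0 despite a scaled count. With the SML FPKM rebuilt 551 of 9974 genes were higher and 558 lower, but this was not run without the filter. With totals equal outside the 50 highest genes 657 were higher and 490 lower. Removing the GC content and length trend left 351 higher and 509 lower. Fatty acid oxidation reached percentile 97.92 at a mean FPKM of at least 5 and OXPHOS complex I 0.88 without matching, and the cause was not tested for any of these. No paired analysis was possible because each group had 1 library. Depth limited 134 of the genes kept to under 30 fragments in all, and 53 of these passed the size rule.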

Other observations

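The 3 tests on the skeletal muscle pattern were chosen after the result was seen, and the genes Moap1 and Malat1 were named after their values were seen. The stress and turnover lists not described above lay within the random range as reported, but single members went far in both directions. In the apoptosis list (3 of 17 higher, 3 lower, median 0.07, percentile 76.5) Ccng1 and Mdm2, both p53 target genes, were 2.29-fold (2.09 to 2.52) and 2.69-fold (2.06 to 3.52) higher, whereas Trp53 itself was 1.70-fold lower (1.37 to 2.12) and Cdkn1a, another p53 target, 1.72-fold lower (1.51 to 1.95). With the GC and length trend removed 2 of 17 were higher and 1 was lower, and Cdkn1a, Hif1a, Hspa5 and Aldh6a1 were under the size rule. Hypoxia response genes (2 of 17 higher, 2 lower, median 0.02, percentile 57.3) included Epas1 (1.73-fold higher, 1.65 to 1.81) and Hif1a (1.76-fold higher, 1.52 to 2.04), the oxygen-sensing factors, beside Ndrg1 (2.10-fold lower, 1.83 to 2.42), with 1 higher and 1 lower after trend removal. The unfolded protein and integrated stress response list had a median of 0.12 at percentile 94.7, with 3 of 28 higher and 2 lower, but percentile 99.1 at a mean FPKM of at least 5 and 98.9 with the highest transcript per symbol. Hspa5, the main chaperone of the endoplasmic reticulum, was 1.65-fold higher (1.56 to 1.74) while Psat1 was 2.42-fold lower (1.57 to 3.84). Branched-chain amino acid catabolism had a median of 0.12 at percentile 97.2, with 2 of 19 higher, Dbt (2.31-fold, 2.07 to 2.57) and Aldh6a1 (1.59-fold, 1.53 to 1.66), and 0 lower.

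The NRF2 antioxidant list (0 of 29 higher, 3 lower, median -0.14, percentile 5.02) had Gsta3 (3.28-fold, 1.68 to 6.99) and Cbr3 (2.40-fold, 1.58 to 3.75) as its lowest members, and it stood at percentile 0.21 once the GC and length trend was removed and 2.19 with a pseudocount of 5. Xenobiotic metabolism (0 of 10 higher, 1 lower, median -0.13, percentile 12.6, but 98.4 for the 7 members with a mean FPKM of at least 5), immediate early genes (1 of 17 higher, 2 lower, median -0.07, percentile 22.8) and autophagy and lysosome genes (0 of 22 past the rule, median -0.05, percentile 36.3) lay within the random range, with Cyp4b1 1.92-fold lower (1.68 to 2.20), Myc 2.31-fold higher (1.29 to 4.24) and Klf2 1.81-fold lower (1.61 to 2.02). Malat1, a nuclear non-coding RNA, had 126 fragments in HFD control and 568 in SML, and Moap1 had 0 and 113.

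Skeletal muscle genes were lower in the SML library, with Acta1 at 881 and 52.5 FPKM. A difference in library scaling or depth would move all genes alike, but the list lay at percentile 0 among matched random lists. Skeletal muscle tissue in the HFD control sample is a candidate explanation and would bring other muscle transcripts too. In a second list 34 of 40 measured muscle genes (85%) were lower by the size rule and 0 higher. This was short of the 90% set for this explanation, and the shortfall depended in part on the pseudocount. Murc, Txlnb and Smtnl2 did not pass the rule but were 1.91-fold, 1.74-fold and 1.52-fold lower by scaled counts. Myom3, Fbp2 and Unc45b had count ratios above 1, at 1.26, 1.44 and 1.13. Muscle tissue stays open as an explanation. It cannot be told apart from an effect of SML on muscle genes in fat cells with 1 library per group.

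The thermogenic list was higher, and its percentile of 99.3 with the trend removed argues against a GC content or transcript length trend between the libraries as the whole cause. Dilution of fat cell RNA by skeletal muscle RNA in the HFD control sample could also raise it. Lipolysis and lipid droplet genes without Fitm1 would then be higher by at least the thermogenic median of 0.15, and their median was 0.034 with a quartile range of 0.25. That median and the upper quartile of 0.079 were both below 0.15, so most of these genes rose by less than dilution needs. Dilution was to be rejected only if the median lay below 0.077 by more than the quartile range, which it did not. This bound used the spread of the members and was so wide that only lower lipolysis genes could have passed it. The test as set therefore could not decide on dilution, and an effect of SML on thermogenic genes stays untested.

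Antigen presentation genes were lower, and the list stayed at percentile 0 after the GC content and transcript length trend was removed, which argues against that trend as the whole cause. Fewer macrophages in the SML sample may account for it. The class I and immunoproteasome members, which most cells express, had a median of -0.75 against -0.49 for the macrophage markers, whose quartile range was 0.49. The class I members thus fell by more than the macrophage markers on this scale, whereas fewer macrophages should lower them by no more. By the median ratio of scaled counts the sets were closer, at 1.70-fold and 1.55-fold lower. The explanation was to be rejected only if the gap between the log2 medians exceeded the quartile range of the macrophage markers, a wide bound that was not passed. The test weighed no other cell type, although endothelial (median -0.33) and mural markers (-0.34) were also lower. T and NK cell markers (-0.12) lay within the random range. By this test fewer macrophages cannot be told apart from lower interferon signalling in other cells. An effect of SML on either stays untested.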
